A study of Mus musculus with 6 samples.

How the data were processed

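RNA was measured in the visual cortex of 6 libraries from mice of a line on the B6.CBA/Tar background that carries a mutation in an untranslated region of Mmp9 (UTRmut). Per the labels, tissue was dissected at postnatal day 28, total RNA was extracted with phenol/chloroform, and libraries were made with the TruSeq Stranded Total RNA kit. There were 2 libraries for each of 3 genotypes: wild type (WT, 0 mutant alleles), heterozygous (het, 1 mutant allele) and homozygous (UTRmut, 2 mutant alleles). Replicate 1 of each genotype was the female and replicate 2 the male, so each cell of genotype and sex held 1 library. The labels do not state whether further animals were pooled in a library or whether libraries shared a litter or a preparation day, and p-values measure only the spread between these samples, part of which may be technical.

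The deposited table holds raw read counts per Ensembl gene for each library, without normalisation and without pooling of replicates. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2, GATK 4.2.3.0, HTSeq 0.6.0 and the genome build GRCm38 were used, with no role or order given. The version of HISAT2, the strand setting of the counting, the annotation release and any filter on reads or genes are not given in the sources used here. In the females the deposited counts of Xist were 6164 to 7056 and those of its antisense gene Tsix were 0 or 1. A low Tsix count alone does not show whether reads from the 2 strands were counted apart. Total RNA libraries hold unspliced and non-polyadenylated RNA, and the removal of ribosomal RNA before sequencing can differ from library to library. Both can move a library's counts without a change in transcription, and the shares of these classes per library are given with the results.

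The table had 55487 genes, of which 26168 had a count of 0 in every library. Symbols were found for 55141 gene identifiers in the reference annotation (GENCODE, mouse, GRCm38), and the other 346, with 0.0332% of all counts, went by identifier. Positions and gene classes came from the same annotation. A symbol shared by several identifiers stayed with the identifier of the highest total count. Total counts per library were 9500090 to 11966579. A count of 0 in a library allowed up to 3 counts, or 0.259 to 0.312 CPM (counts scaled to library size). Folds against a group at 0 were computed against that floor in each library and are lower bounds, and ratios against a group with few counts carry a 95% interval. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Depth limited what could be seen of genes with few counts, Mmp9 and Timp1 among them.

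Genes were kept with the filterByExpr function by genotype (minimum count 10, minimum total 15), which left 16119 genes. Counts were scaled with trimmed mean of M-values (TMM) factors and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test with robust empirical Bayes, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene passed at an adjusted p under 0.05. All 6 libraries entered each fit and shared 1 estimate of the spread. The comparisons were UTRmut against WT, het against WT and UTRmut against het (genotype as a factor, 3 residual degrees of freedom), the change per mutant allele (4), females against males with genotype in the model (2), and the difference between the sexes in the change per allele (2). Standard errors (SE) of log2 folds were taken as the absolute log2 fold divided by the square root of F. CPM values are TMM-scaled and are given as the mean ± SD. Timp1 did not pass the filter and its values came from a fit without it.

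For lists of genes, limma 3.58.1 camera was run on log2 CPM (prior count 2) with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists, each with at least 3 tested genes. Beside it, camera was run with the correlation estimated per list, and fry as a test of each list on its own. The lists held metalloproteases and their inhibitors, reported MMP-9 substrates, extracellular matrix, activity-regulated genes, synapse, cell types, possible carry-over of dissection, RNA quality and sex chromosome genes, and the result of each is given in the report. The lists, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined, apart from the alternative and the tests that the closing section names as chosen later.

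The rule named Mmp9 and Timp1 to Timp4 in every comparison. It further named, in each direction, up to 10 genes with the smallest p among those that passed and whose groups did not overlap in log2 CPM, or, where fewer than 3 passed, the 3 genes with the smallest unadjusted p, named as not passing. For the change per allele, genotype means in order took the place of groups that do not overlap. For the difference between the sexes, opposite signs of UTRmut minus WT in females and males took that place. Up to 4 members with the smallest p were named of each list past the threshold and of the lists of metalloproteases, MMP-9 substrates, perineuronal net and immediate-early genes. Predicted gene models and pseudogenes were counted and not named. Genes outside this rule are given as chosen after their values were seen. Some results that the rule would name are withheld and not reported here.

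Alternatives were DESeq2 1.42.0 size factors in the same test, library size alone, no filter or a stricter filter on low counts (1 CPM in every library of a genotype), the DESeq2 Wald test, no robust estimation, each library left out in turn, removal of mitochondrial, ribosomal and small structural RNAs, the replicate number as a block, only the libraries of the 2 genotypes compared, no genotype term for the comparison of the sexes, and a threshold of 0.1. Leaving out 1 library left its group with 1, whose spread was assumed to be that of the other groups. In the fit of the difference between the sexes it left a cell of the design empty. Pairs of libraries of a genotype were checked for repeated deposition by a chi-square test of their counts. The chi-square per degree of freedom was 8.38 for WT, 4.49 for het and 8.50 for UTRmut, far above sampling noise, and all 6 libraries were counted separately.

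The fits were tested on simulated counts with the means and library sizes of the real genes, 16119 genes of which 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. For UTRmut against WT the test recovered 43.3%, 67.2% and 87.9% of these, and for het against WT 35.8%, 62.7% and 84.9%. For UTRmut against het it recovered 29.9%, 58.2% and 89.4%, and for the change per allele 74.6%, 89.6% and all. In the simulation per allele each fold was given per mutant allele and was thus squared in UTRmut. Its shares cannot be set beside those of the comparisons of 2 groups. For females against males the shares were 40.3%, 68.7% and 92.4%, and for the difference between the sexes in the allele effect 38.8%, 67.2% and 92.4%. In this last simulation the fold was likewise given per mutant allele, in females alone. Between 13 and 20 unchanged genes were called in these simulations. For UTRmut against WT these were 17, beside 29, 45 and 58 changed genes recovered, in the order of the folds. For UTRmut against het they were 20, beside 20, 39 and 59. In every comparison the share of unchanged genes among the calls was above the threshold set on the adjusted p. The adjusted p of the real data may thus understate the share of false calls. The simulated genes varied independently, without the shifts of many genes at once that were seen between the real libraries. The shares recovered may thus be too high for the real data. In the list test, a 1.5-fold rise given to the 17 members of the perineuronal net list was found, together with 1 list that had not been raised. Empty columns of the table were left out.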

Results

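The data were raw read counts from total RNA of the visual cortex of mice at postnatal day 28. The mice belonged to a line with a mutation in an untranslated region of Mmp9, the gene of matrix metalloproteinase 9, a secreted protease that acts on the extracellular matrix around synapses. There were 2 libraries each of wild type (WT), heterozygous (het) and homozygous (UTRmut) mice, in each case 1 female (replicate 1) and 1 male (replicate 2). Total counts were 10061225 and 11622460 in WT, 9500090 and 10598963 in het, and 10916813 and 11966579 in UTRmut, and between 23353 and 23845 genes had at least 1 count in a library. The design asks how the cortical transcriptome differed with the mutant allele, and 16119 genes were tested.

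Mmp9 transcript was scarce in every library. The gene (ENSMUSG00000017737) lies on chromosome 2 of GRCm38, from 164940780 to 164955850 on the plus strand, and its main transcript has 13 exons, with the 3' untranslated region from 164954904 to 164955850 in exon 13. The labels say neither which of the 2 untranslated regions was changed nor which bases. Mmp9 had 4 and 9 counts in the WT libraries, 9 and 9 in het and 8 and 16 in UTRmut, or 0.582 ± 0.277, 0.889 ± 0.0680 and 1.07 ± 0.456 CPM (SD, n = 2 each). The log2 fold was 0.86 (SE 0.58) for UTRmut against WT and 0.58 (SE 0.61) for het against WT, and neither passed (edgeR, Benjamini-Hochberg adjusted p of at least 0.9988). The inhibitor Timp1 was as scarce, at 0.582 ± 0.277 CPM in WT, 0.749 ± 0.266 in het and 0.678 ± 0.0975 in UTRmut. The log2 folds of the inhibitors Timp2, Timp3 and Timp4 for UTRmut against WT were 0.00 (SE 0.09), 0.09 (SE 0.18) and 0.17 (SE 0.16), and for het against WT -0.01 (SE 0.09), 0.15 (SE 0.18) and -0.01 (SE 0.16). Timp1 had 0.20 (SE 0.66) and 0.32 (SE 0.66). Per mutant allele Timp1 to Timp4 had 0.10 (SE 0.32), 0.00 (SE 0.04), 0.04 (SE 0.09) and 0.09 (SE 0.07), and in UTRmut against het -0.12 (SE 0.65), 0.01 (SE 0.09), -0.06 (SE 0.18) and 0.18 (SE 0.16). None passed.

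In UTRmut against WT, 1 gene rose and 0 fell. The count depended on the libraries and the filter: 72 were higher and 31 lower without WT replicate 2, and 15 higher and 12 lower without a filter on low counts. Catspere1, annotated as an unprocessed pseudogene on chromosome 1 (177808550 to 177962233), had 0 counts in both WT libraries and 52 and 74 in the UTRmut libraries. It was at least 20.6-fold higher in UTRmut, with the floor of 3 counts per WT library (edgeR, Benjamini-Hochberg adjusted p = 0.00557), and was named after its values were seen because the naming rule left out pseudogenes. Catspere2, a neighbour of the same family that encodes a subunit of the sperm calcium channel CatSper (177983423 to 178172704), had 7.50 ± 0.382 CPM in WT and 20.96 ± 2.97 in UTRmut. Its log2 fold of 1.48 (SE 0.21) did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.107), and passed with the replicate block (sex) at 0.0112 (range over 16 alternatives 1.08e-12 to 0.708). Counts of either gene are uncertain where reads match both. The Catspere1 call was lost without UTRmut replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0611, range over 16 alternatives 2.00e-24 to 0.0611). At an unadjusted p under 0.05 there were 437 genes, and DESeq2 with Benjamini-Hochberg adjustment called 5: Catspere1, Catspere2, CT010467.1, Fos and mt-Rnr1.

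Among the genes with the smallest p that did not pass, mt-Rnr1, the small ribosomal RNA of mitochondria, had 4101 ± 399 CPM in WT and 7540 ± 1425 in UTRmut (log2 fold 0.88, SE 0.12). Dbndd2 had a log2 fold of 0.55 (SE 0.11). On the lower side, Htr2c, a serotonin receptor, had 18.4 ± 1.34 CPM in WT and 7.94 ± 1.32 in UTRmut (log2 fold -1.21, SE 0.22). Npsr1, the receptor of neuropeptide S, and Mki67, a marker of proliferating cells, had log2 folds of -1.52 (SE 0.31) and -2.69 (SE 0.62). The adjusted p of these 5 genes was 0.388 to 0.999 (edgeR, Benjamini-Hochberg). With the replicate block (sex) mt-Rnr1 passed at 0.0222 (range over 15 alternatives 1.38e-19 to 0.770).

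**Figure D1:**
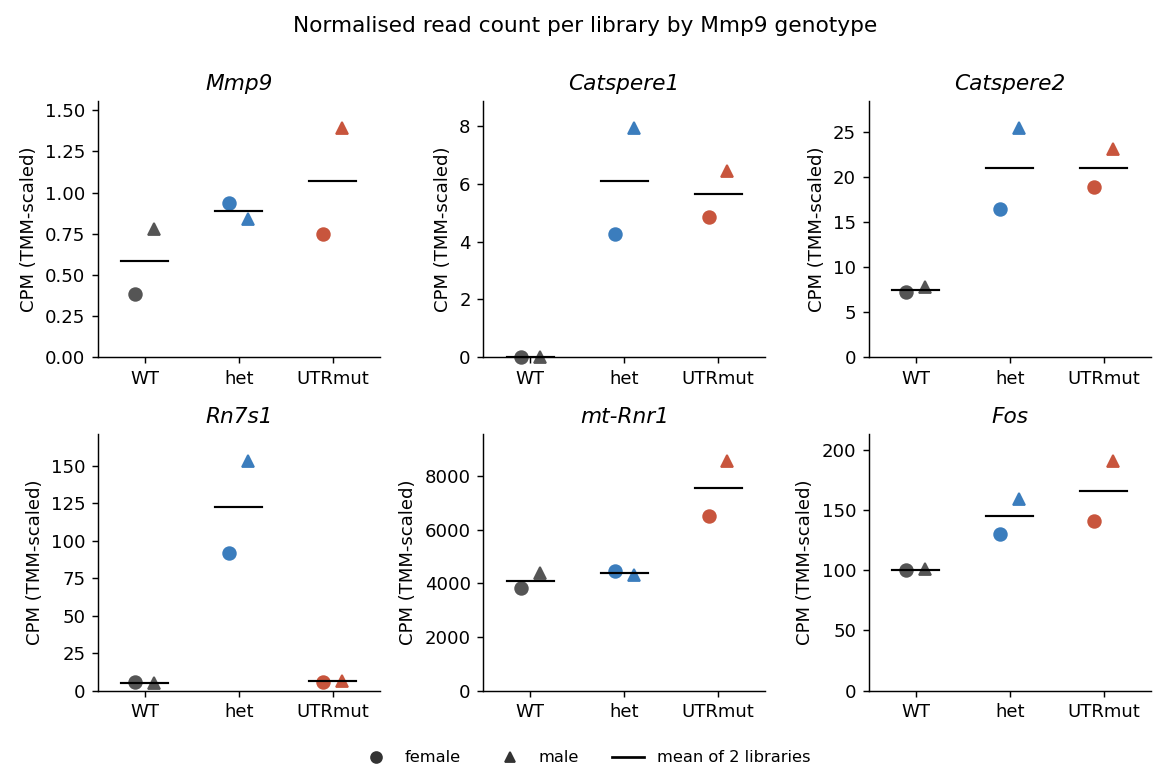
Normalised read count (TMM-scaled CPM, linear axes from 0) of 6 genes in each library by genotype, circles for females, triangles for males and bars for the mean of 2 libraries. Catspere1 is at 0 in both WT libraries, Rn7s1 is high in both het libraries, and Mmp9 lies near or below 1.4 CPM throughout.

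Immediate-early and later activity-regulated genes lay higher on average in UTRmut than in WT, the later ones only through the WT female library. Of 28 immediate-early genes, which neurons switch on within minutes of firing, 25 had a positive log2 fold, with a median of 0.39 (camera, Benjamini-Hochberg adjusted p = 1.40e-09; adjusted p = 0.899 with an estimated correlation). Fos had 100 ± 0.550 CPM in WT and 166 ± 35.1 in UTRmut (log2 fold 0.72, SE 0.14), Egr2 had a log2 fold of 0.80 (SE 0.23), Gadd45b 0.60 (SE 0.17) and Nr4a3 0.43 (SE 0.15). In edgeR none of the 28 passed over all genes tested, and Fos alone passed adjusted over the list alone. Fos passed over all genes with DESeq2, and in edgeR without a filter on low counts and without UTRmut replicate 1 (Benjamini-Hochberg adjusted p over 16 alternatives 2.39e-09 to 0.9999). Of 20 later activity-regulated genes 16 were positive, with a median of 0.28 (camera, Benjamini-Hochberg adjusted p = 0.000769; adjusted p = 0.899 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Rgs2 and Plk2 had log2 folds of 0.32 (SE 0.12) and 0.24 (SE 0.10), Scg2 had 0.24 (SE 0.11) and Tac1, the precursor of substance P, had -0.42 (SE 0.20). The WT female library stood apart from the others on both lists: its median level relative to the mean of the 6 libraries was -0.45 and -0.41 on the log2 scale, against 0.04 and 0.17 in the WT male. The UTRmut female and male had 0.13 and 0.26 on the immediate-early list and 0.16 and 0.11 on the later list. On the later list both thus lay below the WT male.

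Transcripts of ribosomal proteins and of the respiratory chain also lay slightly higher in UTRmut than in WT. The median log2 fold was 0.14 over 38 ribosomal protein genes, 37 of them positive (camera, Benjamini-Hochberg adjusted p = 2.13e-08; adjusted p = 0.899 with an estimated correlation), and 0.12 over 27 nuclear-encoded respiratory chain subunits, all 27 positive (camera, Benjamini-Hochberg adjusted p = 3.46e-05; adjusted p = 0.899 with an estimated correlation). Rps16, Rpl35, Rps27 and Rps29 had log2 folds of 0.39 (SE 0.13), 0.29 (SE 0.11), 0.24 (SE 0.10) and 0.23 (SE 0.10), and Atp5j, Ndufa4 and Cox6a1 of 0.26 (SE 0.10), 0.21 (SE 0.10) and 0.20 (SE 0.10). In each list 0 genes passed over all genes or adjusted over the list alone. The WT female library was lowest on these lists too, at -0.15 on both, against 0.01 and 0.02 in the WT male. The UTRmut female and male had 0.04 and 0.11 on the ribosomal list and 0.007 and 0.13 on the respiratory chain list. On the latter the UTRmut female thus lay below the WT male. Without WT replicate 1 the camera calls of the late activity, respiratory chain and ribosomal lists were lost (Benjamini-Hochberg adjusted p = 0.709 with the opposite sign, 0.389 and 0.0848), the respiratory chain call was also lost without UTRmut replicate 2 (0.156), and the immediate-early call held in all 6 fits that left out a library (up to 0.00635). With the library's share of TEC-class transcripts as a covariate, chosen after the data were seen, the same 3 calls were lost (camera, Benjamini-Hochberg adjusted p = 0.279, 0.393 and 0.0636). Over 12 alternatives the camera and fry adjusted p ranged from 4.26e-12 to 0.981 for immediate-early, 1.93e-10 to 0.981 for late activity, 3.85e-09 to 0.981 for ribosomal and 1.51e-06 to 0.981 for respiratory chain genes (Benjamini-Hochberg).

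**Figure D2:**
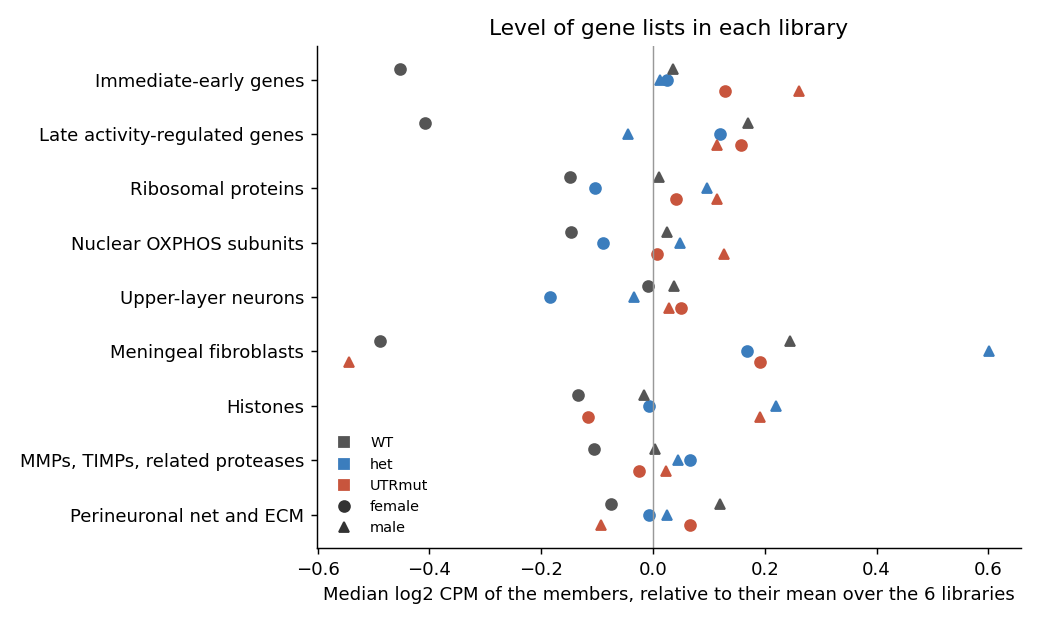
Median log2 CPM of the members of 9 gene lists in each library, relative to each member's mean over the 6 libraries, coloured by genotype and shaped by sex. The WT female library is lowest for immediate-early (-0.45) and late activity-regulated genes (-0.41), and meningeal fibroblast genes range from -0.54 in the UTRmut male to 0.60 in the het male.

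Lists tied to the protease itself stayed below the threshold in UTRmut against WT. Of 20 metalloproteases, inhibitors and related proteases 10 were positive (median 0.03). Plau was at 0.35 (SE 0.29), Plat, the tissue plasminogen activator, at 0.13 (SE 0.10) and Adam17 at -0.18 (SE 0.13). Of 20 reported MMP-9 substrates 9 were positive (median -0.01). Tnc was at -0.51 (SE 0.20), Ephb2 at -0.25 (SE 0.14) and Sdc3 at -0.14 (SE 0.09). Of 17 perineuronal net and matrix genes 6 were positive (median -0.08). Acan, the core protein aggrecan, was at 0.51 (SE 0.27), Sema3a at 0.27 (SE 0.15) and Tnr at -0.17 (SE 0.09). No member of the 3 lists passed over all genes or adjusted over the list alone (0 genes, edgeR with Benjamini-Hochberg adjustment; DESeq2 called none of them), and the camera adjusted p were 0.426, 0.766 and 0.6001 (Benjamini-Hochberg).

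The other lists did not pass in UTRmut against WT. Median log2 folds were 0.10 for critical-period genes, 0.01 for the glutamatergic synapse, 0.05 for interneurons, 0.05 for upper-layer and -0.06 for deep-layer neurons, and 0.02 for regulators of mRNA translation. Among glia and vessels they were 0.07 for astrocytes, -0.09 for oligodendrocytes, -0.07 for their precursors, 0.02 for microglia, 0.17 for inflammatory genes, -0.15 for endothelial and mural cells and -0.08 for basement membrane. Lists of possible carry-over had medians of -0.16 for meninges, -0.71 for choroid plexus, -0.74 for red blood cells, 0.07 for hippocampus and 0.06 for striatum and thalamus. Proliferating cells had -0.33, heat shock 0.03, histones 0.13, structural noncoding RNA -0.21, mitochondrially encoded mRNAs 0.04, genes escaping X inactivation -0.06 and Y-linked genes 0.13. The smallest adjusted p of these lists was 0.0543, for red blood cells (camera, Benjamini-Hochberg). Adjusted over the list alone, Hba-a1 (log2 fold -0.84, SE 0.18) and Alas2 (-1.001, SE 0.27) of the blood list, Mki67 of the proliferation list and C1ql2 (-1.19, SE 0.32) of the hippocampal list passed, chosen after their values were seen, and none passed over all genes.

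In het against WT, 2 genes rose and 0 fell. Without WT replicate 2, 26 were higher and 4 lower, and without a filter on low counts 8 were higher and 5 lower. Catspere1 had 41 and 85 counts in het and 0 in both WT libraries, at least 22.3-fold higher with the floor of 3 counts per library (edgeR, Benjamini-Hochberg adjusted p = 0.00430). Rn7s1, an RNA component of the signal recognition particle on chromosome 12 (69159295 to 69159594), had 57 and 56 counts in WT and 880 and 1637 in het, a log2 fold of 4.57 (SE 0.29; edgeR, Benjamini-Hochberg adjusted p = 0.00784). Rn7s2, a near-identical copy at 69361182 to 69361481 named after its values were seen, had 554 and 296 counts in WT and 325 and 394 in het (log2 fold -0.15, SE 0.35), and reads that match both copies leave the counts of each uncertain. Catspere2 had a log2 fold of 1.48 (SE 0.21) and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0741), and passed with the replicate block (sex) at 0.0132 (range over 16 alternatives 2.26e-12 to 0.9997). The Rn7s1 call was lost without WT replicate 1, WT replicate 2, UTRmut replicate 1 or UTRmut replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.577, 0.314, 0.0671 and 0.0660, range over 15 alternatives 1.62e-115 to 0.577), with log2 folds of 4.15 to 4.89 over the 6 fits that left out a library. At an unadjusted p under 0.05 there were 382 genes, and DESeq2 called 3, Catspere2 beside these.

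Genes with the smallest p that did not pass in het against WT were Apod, the lipid carrier apolipoprotein D (log2 fold 0.61, SE 0.13), Slc7a11, the cystine and glutamate exchanger (0.42, SE 0.10), Scoc (-0.72, SE 0.13), the integrin gene Itga4 (-0.54, SE 0.12) and the bromodomain gene Brd9 (-0.40, SE 0.10). In the metalloprotease list 13 of 20 genes were positive in het, with a median of 0.08 (camera, Benjamini-Hochberg adjusted p = 0.0444; adjusted p = 0.958 with an estimated correlation). Mmp14, a membrane-bound matrix metalloproteinase, had 5.58 ± 0.435 CPM in WT and 10.02 ± 0.487 in het (log2 fold 0.85, SE 0.22) and was the 1 member that passed adjusted over the list alone, with 0 over all genes. Plat had 0.29 (SE 0.10), Mmp2 0.53 (SE 0.40) and Serpine2 -0.15 (SE 0.10). MMP-9 substrates (median 0.01) and perineuronal net genes (median -0.02) did not pass. Sdc3 was at -0.24 (SE 0.09), Bcan at 0.16 (SE 0.10), Itgb1 at 0.09 (SE 0.10). Acan was at 0.38 (SE 0.28), Csgalnact1 at 0.26 (SE 0.13) and Has3 at -0.44 (SE 0.33).

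Meningeal, immediate-early, ribosomal protein and histone lists lay higher in het than in WT, and upper-layer neuron genes lay lower. Of 13 meningeal and fibroblast genes 10 were positive with a median of 0.48 (camera, Benjamini-Hochberg adjusted p = 0.0263, and adjusted p = 0.958 with an estimated correlation). Among them were Ptgds, prostaglandin D synthase, at 0.79 (SE 0.42), Dcn at 0.68 (SE 0.30), Slc22a6 at 0.68 (SE 0.34) and Aldh1a2 at 0.48 (SE 0.30). Of 28 immediate-early genes 24 were positive (median 0.21; camera, Benjamini-Hochberg adjusted p = 0.00604, and adjusted p = 0.958 with an estimated correlation). Fos was at 0.53 (SE 0.14), Gadd45b at 0.44 (SE 0.18), Nr4a3 at 0.39 (SE 0.15) and Dusp1 at -0.40 (SE 0.13). Of 38 ribosomal protein genes 35 were positive (median 0.07; camera, Benjamini-Hochberg adjusted p = 0.0243, and adjusted p = 0.958 with an estimated correlation). Rps15, Rplp0, Rpl18 and Rps19 were at 0.19 (SE 0.11), 0.17 (SE 0.10), 0.16 (SE 0.11) and 0.15 (SE 0.10). All 10 histone genes were positive (median 0.31; camera, Benjamini-Hochberg adjusted p = 0.00637, and adjusted p = 0.958 with an estimated correlation). Hist1h1e was at 0.32 (SE 0.14), Hist1h2be at 0.33 (SE 0.22), Hist1h4d at 0.30 (SE 0.14) and Hist1h1c at 0.18 (SE 0.14). Of 14 upper-layer genes 12 were negative (median -0.16; camera, Benjamini-Hochberg adjusted p = 0.0243, and adjusted p = 0.958 with an estimated correlation). Scnn1a, a marker of the input layer, was at -0.99 (SE 0.36), Rasgrf2 at -0.20 (SE 0.09), Cux1 at -0.17 (SE 0.10) and Rorb at -0.16 (SE 0.10). Structural noncoding RNA genes lay higher (6 of 10 positive, median 0.10; camera, Benjamini-Hochberg adjusted p = 0.0231, and adjusted p = 0.958 with an estimated correlation). Rn7sk was at 0.22 (SE 0.07), Neat1 at 0.42 (SE 0.27) and Malat1 at 0.20 (SE 0.16). Over all genes 1 member of these lists passed, Rn7s1, and adjusted over the list alone Rn7s1, Rn7sk and Mmp14 did. The calls of 5 lists (histone, immediate-early, meningeal, metalloprotease and ribosomal) were lost without WT replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0974 to 0.766) and without het replicate 2 (0.103 to 0.582), and those of the noncoding and upper-layer lists were lost without het replicate 1 (0.0758 and 0.309) and WT replicate 2 (0.971 and 0.178). Over 12 alternatives the camera and fry adjusted p of the 7 lists ranged from 6.75e-09 to 0.999 (Benjamini-Hochberg), and the opposite sign was found for the immediate-early, meningeal and ribosomal lists without WT replicate 1, the noncoding list without WT replicate 2 and the ribosomal list without het replicate 2. Without a filter on low counts only the immediate-early call held, and with the TEC share as a covariate the meningeal and metalloprotease calls were lost (0.0785 and 0.0932), as they were with the replicate block (sex) (0.0732 and 0.0739; camera, Benjamini-Hochberg).

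In UTRmut against het, 0 genes rose and 2 fell. Without either WT replicate 5 were higher and 5 lower, and without a filter on low counts 13 were higher and 15 lower. Rn7s1 had 880 and 1637 counts in het and 64 and 72 in UTRmut (log2 fold -4.32, SE 0.28; edgeR, Benjamini-Hochberg adjusted p = 0.0193). Gm37176, an unspliced gene model on chromosome 17 (51859167 to 51863217) named after its values were seen, had 84 and 89 counts in het and 17 and 19 in UTRmut, with 39 and 26 in WT (log2 fold -2.39, SE 0.32; edgeR, Benjamini-Hochberg adjusted p = 0.0234). The call of Rn7s1 was lost without WT replicate 1, WT replicate 2, UTRmut replicate 1 or UTRmut replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.645, 0.691, 0.169 and 0.207, range over 15 alternatives 1.17e-110 to 0.691), and that of Gm37176 without either het library or either UTRmut library (0.174, 0.248, 0.201 and 0.265, range over 16 alternatives 9.99e-10 to 0.265). At an unadjusted p under 0.05 there were 452 genes and DESeq2 called 6, among them mt-Rnr1, whose log2 fold was 0.78 (SE 0.12; edgeR, Benjamini-Hochberg adjusted p = 0.529, and 0.0499 with the replicate block (sex), range over 15 alternatives 1.41e-15 to 1). Other genes with the smallest p that did not pass were the phosphatase gene Dusp1 (log2 fold 0.52, SE 0.13), Scoc (0.48, SE 0.13), Zfpm2 (-0.60, SE 0.14), Enpp6, a gene of newly forming oligodendrocytes (-0.68, SE 0.17), and Tmem267 (-1.37, SE 0.36). Mmp9 had a log2 fold of 0.28 (SE 0.55).

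Upper-layer neuron, immediate-early, ribosomal protein and respiratory chain lists lay higher in UTRmut than in het, while meningeal, basement membrane and structural noncoding lists lay lower. Of 14 upper-layer genes 10 were positive with a median of 0.25 (camera, Benjamini-Hochberg adjusted p = 0.00368, and adjusted p = 0.937 with an estimated correlation). Rorb, Wfs1, Lamp5 and Rasgrf2 were at 0.33 (SE 0.10), 0.34 (SE 0.14), 0.26 (SE 0.11) and 0.22 (SE 0.09). Of 28 immediate-early genes 25 were positive (median 0.20; camera, Benjamini-Hochberg adjusted p = 0.00489, and adjusted p = 0.937 with an estimated correlation). Ier2 was at 0.60 (SE 0.35), Nr4a1 at 0.31 (SE 0.17) and Egr4 at 0.25 (SE 0.17). Of 38 ribosomal protein genes 32 were positive (median 0.08; camera, Benjamini-Hochberg adjusted p = 0.00489, and adjusted p = 0.937 with an estimated correlation). Rps16, Rpl35, Rpl38 and Rps29 were at 0.32 (SE 0.13), 0.25 (SE 0.11), 0.21 (SE 0.09) and 0.20 (SE 0.10). Of 27 respiratory chain genes 24 were positive (median 0.09; camera, Benjamini-Hochberg adjusted p = 0.00785, and adjusted p = 0.937 with an estimated correlation). Uqcrq was at 0.20 (SE 0.11), Atp5j at 0.18 (SE 0.10) and Ndufs1 at 0.13 (SE 0.09). Of 13 meningeal genes 12 were negative (median -0.42; camera, Benjamini-Hochberg adjusted p = 0.00489, and adjusted p = 0.937 with an estimated correlation). Slc22a6 was at -0.93 (SE 0.35), Col3a1 at -0.92 (SE 0.37), Mgp at -0.78 (SE 0.44) and Dcn at -0.45 (SE 0.30). Of 17 basement membrane genes 14 were negative (median -0.14; camera, Benjamini-Hochberg adjusted p = 0.0392, and adjusted p = 0.937 with an estimated correlation). Col18a1 was at -0.58 (SE 0.38), Lama1 at -0.52 (SE 0.31), Lamb2 at -0.31 (SE 0.15) and Lamc1 at -0.21 (SE 0.13). All 10 structural noncoding genes were negative (median -0.27; camera, Benjamini-Hochberg adjusted p = 0.00368, and adjusted p = 0.937 with an estimated correlation). Neat1 was at -0.76 (SE 0.27), Malat1 at -0.29 (SE 0.16) and Rn7sk at -0.10 (SE 0.07). Over all genes or adjusted over the list alone Rn7s1 was the 1 member of these lists that passed. Metalloproteases (median 0.00), MMP-9 substrates (median 0.02) and perineuronal net genes (median 0.01) did not pass. Mmp14 was at -0.59 (SE 0.21), Mmp2 at -0.83 (SE 0.41), Adam17 at -0.32 (SE 0.13) and Serpine2 at 0.21 (SE 0.09). Tnc was at -0.59 (SE 0.20), Ephb2 at -0.26 (SE 0.14) and Itga5 at 0.43 (SE 0.34). Crtac1 was at 0.16 (SE 0.10), Bcan at -0.14 (SE 0.10) and Tnr at -0.10 (SE 0.09). Without UTRmut replicate 2 all of these calls but that of upper-layer genes were lost (camera, Benjamini-Hochberg adjusted p = 0.0891 to 0.900), without het replicate 1 those of immediate-early, respiratory chain, ribosomal and upper-layer genes were (0.0653 to 0.837), and without het replicate 2 those of basement membrane and meningeal genes were (0.452 and 0.378). The basement membrane list had the opposite sign without UTRmut replicate 2, and the ribosomal list without het replicate 1. Over 12 alternatives the camera and fry adjusted p of the 7 lists ranged from 2.46e-06 to 0.953 (Benjamini-Hochberg). With the TEC share as a covariate the immediate-early, respiratory chain and ribosomal lists had the opposite sign (0.903, 0.850 and 0.709), and the noncoding call was lost (0.185). The basement membrane call was lost with the replicate block (sex) and without a filter on low counts (0.114 and 0.123; camera, Benjamini-Hochberg).

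Per mutant allele, taken over all 6 libraries, 0 genes passed (edgeR, smallest Benjamini-Hochberg adjusted p = 0.416). At an unadjusted p under 0.05 there were 503 genes, and DESeq2 with Benjamini-Hochberg adjustment called 3, of which Fos and Tiparp were higher and Htr2c was lower. Htr2c had 18.4 ± 1.34, 12.4 ± 4.01 and 7.94 ± 1.32 CPM in WT, het and UTRmut, a log2 change of -0.60 per allele (SE 0.10). Npsr1 had -0.75 (SE 0.15) and Mki67 -1.24 (SE 0.29), and the genes with the smallest p on the higher side were Dbndd2 at 0.27 (SE 0.06), Chrdl1, a secreted regulator of bone morphogenetic protein signalling, at 0.28 (SE 0.07) and Fos at 0.36 (SE 0.08). None of these passed in edgeR. Mmp9 had a log2 change of 0.42 per allele (SE 0.28). Without WT replicate 2 the count was 36 genes, and without WT replicate 1, UTRmut replicate 1 or het replicate 2 it was 1.

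UTRmut against WT and het against WT share the WT libraries. Across genes, which are not independent replicates, their log2 folds had a correlation of 0.450, against 0.494 between simulated unchanged groups set against shared controls, and a covariance of 0.0379 against 0.0534 (SD 0.00510 over 50 simulations). Neither observed value exceeded that of shared controls alone. The covariance lay below the simulated mean by more than the SD, so the simulation did not match the spread of the real libraries. Whether the comparisons share a change beyond the shared controls thus cannot be told from it. The comparisons had 1 call in common, Catspere1, against 0.580 in the simulations and 0.000124 for independent lists, and the 2 WT libraries could not be divided with 2 left for each comparison.

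Ribosomal RNA took a larger share of counts in the UTRmut libraries. Mitochondrial rRNA made up 6.31% and 8.69% of counts in UTRmut, 4.95% and 5.23% in WT and 5.78% and 5.07% in het. Nuclear rRNA made up 0.261% and 0.191% in UTRmut, 0.153% and 0.133% in WT and 0.156% and 0.123% in het. Transcripts of the TEC class, unspliced gene models, made up 0.751% of counts in the WT female and 0.680% in the het female, against 0.452% to 0.523% in the other 4 libraries. No test was run on these shares. The first principal component (34.6% of variance) placed the WT female and het female at one end, at -32.0 and -18.8, and the males at 12.1 to 18.9.

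**Figure D3:**
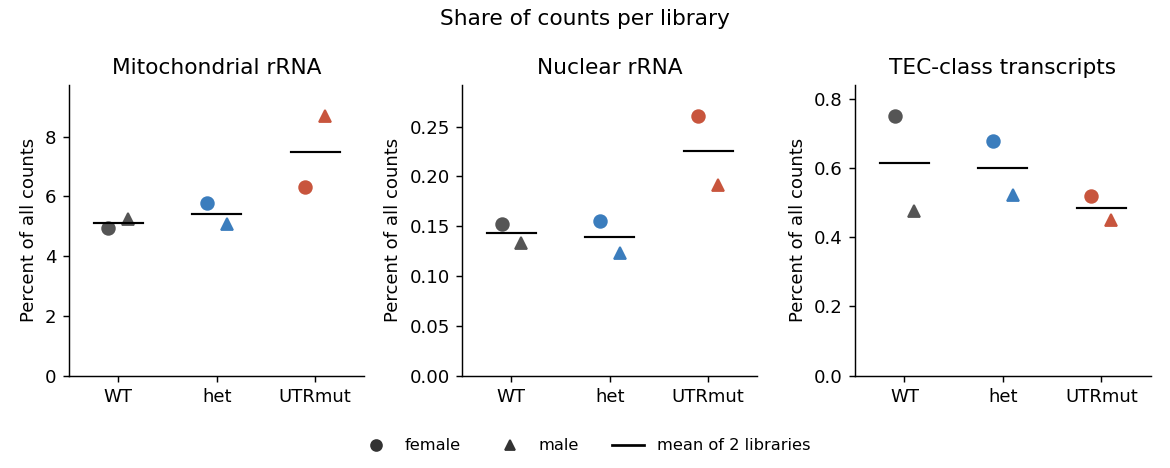
Percent of all counts in mitochondrial rRNA, nuclear rRNA and TEC-class transcripts per library by genotype, circles for females, triangles for males and bars for the mean of 2 libraries. Both rRNA classes are highest in the UTRmut libraries, and the TEC share is highest in the WT female (0.751%).

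Females differed from males in Y-linked genes, as a check of the labels. With genotype in the model, 1 gene was higher and 5 were lower in females, and with scaling by library size alone 3 were higher and 6 lower. Without a filter on low counts 66 were higher and 26 lower. Kdm5d had 0 counts in the 3 females and was at least 142-fold lower in females, with the floor of 3 counts per library. The male to female ratio was 1443 for Uty (95% counting interval 259 to 57020), 635 for Eif2s3y (176 to 5249) and 913 for Ddx3y (312 to 4430). All 4 Y-linked genes passed over all genes and adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 6.15e-09 to 6.81e-08). The other genes, chosen after their values were seen, were Pttg1, securin, with 1, 2 and 1 counts in females and 2, 44 and 52 in the WT, het and UTRmut males (edgeR, Benjamini-Hochberg adjusted p = 0.0212), and the X-linked noncoding C230004F18Rik, with 259 ± 11.1 CPM in females and 176 ± 17.8 in males (SD, n = 3; log2 fold 0.56, SE 0.07; edgeR, Benjamini-Hochberg adjusted p = 0.0101). Both were lost without any 1 of the het and UTRmut libraries (edgeR, Benjamini-Hochberg adjusted p = 0.0530 to 0.999, range over the alternatives of both 2.55e-13 to 0.999). At an unadjusted p under 0.05 there were 1127 genes and DESeq2 called 8. Without WT replicate 1, 154 were higher and 42 lower, and without WT replicate 2, 155 and 42.

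The 8 measured genes that escape X inactivation, Xist among them, were all higher in females, with a median log2 fold of 0.43 (camera, Benjamini-Hochberg adjusted p = 1.37e-06; adjusted p = 0.347 with an estimated correlation). Over all genes 0 passed, and 7 passed adjusted over the list alone (edgeR). Kdm6a, Eif2s3x, Jpx and Ftx had log2 folds of 0.47 (SE 0.10), 0.40 (SE 0.09), 0.66 (SE 0.19) and 0.46 (SE 0.12), Kdm5c, Ddx3x and Pbdc1 had 0.21 (SE 0.07), 0.15 (SE 0.06) and 0.16 (SE 0.12), and Fam227b, outside the list and not passing, had 2.79 (SE 0.53). Xist had 656 ± 12.7 CPM in females and 8.33 ± 12.8 in males, with 268 counts in the WT male against 15 and 5 in the other males, and did not pass over all genes (edgeR, Benjamini-Hochberg adjusted p = 0.683). Xist passed with DESeq2, in edgeR without robust estimation, and without either WT library. The Y-linked list call had an adjusted p of 0.347 with an estimated correlation. Lists lower in females were ribosomal proteins (38 of 38 negative, median -0.14), respiratory chain subunits (27 of 27, median -0.15), heat shock (16 of 16, median -0.16), immediate-early (25 of 28, median -0.18), late activity (18 of 20, median -0.14), histone (9 of 10, median -0.20) and oligodendrocyte genes (18 of 20, median -0.11). Their camera adjusted p were 6.77e-09 to 0.0427 (Benjamini-Hochberg), and none held (adjusted p = 0.347 to 0.942 with an estimated correlation). The WT female stood apart in several of these: its level was -0.45 for immediate-early, -0.41 for late activity and -0.16 for heat shock genes, against 0.03 and 0.13, 0.12 and 0.16, and -0.02 and 0.05 in the het and UTRmut females. Mmp9 had a log2 fold of -0.55 (SE 0.45) and did not pass, nor did Timp1 to Timp4, with 0.05 (SE 0.54), 0.06 (SE 0.07), -0.09 (SE 0.16) and -0.04 (SE 0.13).

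The change per mutant allele differed between the sexes in 194 genes, 144 with a higher change in females and 50 with a lower one. No cell of this fit held replicate libraries. Its spread came only from how far each het library lay from the line between WT and UTRmut of its sex. The common dispersion, the shared estimate of the spread, was 0.00443 in this fit and 0.0108 in the fit of the genotypes. SE and adjusted p below thus do not measure a spread between replicates. A higher change in females was found for Kcnj10, an inward-rectifier potassium channel of astrocytes, with a difference of 0.74 on the log2 scale (SE 0.08), Rnd3 with 0.82 (SE 0.11), Zbtb20 with 0.66 (SE 0.08), Epas1, a hypoxia-inducible transcription factor, with 0.65 (SE 0.09), Msmo1, an enzyme of sterol synthesis, with 0.62 (SE 0.09), and Myh9, a nonmuscle myosin, with 0.58 (SE 0.08). Egr1 had 0.55 (SE 0.07), Mapk4 0.55 (SE 0.07) and the chaperone gene Hsph1 0.50 (SE 0.07). Baiap2l1 had 2 counts in the WT and het females, 146 in the UTRmut female and 179 to 241 in the males, and its difference of 4.64 was 0.31 without UTRmut replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.979). A lower change in females was found for the histone gene Hist4h4 at -1.44 (SE 0.15), Etnppl, an astrocytic enzyme, at -0.81 (SE 0.11), Fam214a at -0.73 (SE 0.10), Junb at -0.67 (SE 0.10), Rps6ka5 at -0.55 (SE 0.11), Leng8 at -0.47 (SE 0.08), Eml2 at -0.47 (SE 0.07), Atp11b at -0.42 (SE 0.07), the nuclear noncoding RNA Miat at -0.42 (SE 0.08) and the splicing factor gene Luc7l3 at -0.38 (SE 0.07). The adjusted p of these 20 genes were 0.000104 to 0.0170 (edgeR, Benjamini-Hochberg). Without WT replicate 1, 15 of the 20 were lost (0.0524 to 0.564), without UTRmut replicate 1, 8 were (0.0512 to 0.979), and without WT replicate 2, 8 were (0.0797 to 0.673). Kcnj10, Hist4h4 and Zbtb20 passed in all 6 fits that left out a library. Opposite directions in the 2 sexes were a condition of naming these genes and were found in 55.6% of all genes tested. In Kcnj10 the log2 ratio of UTRmut to WT was 1.06 in females and -0.42 in males.

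By list, the immediate-early genes had 5 members with a higher change in females and 1, Junb, with a lower one (Arc, Egr1, Fosb, Fosl2 and Ier5 were the 5), and the median over 28 was 0.22 (camera, Benjamini-Hochberg adjusted p = 0.00745; adjusted p = 0.601 with an estimated correlation). The shift covered most lists: camera called 18 of the 32, all 18 with a higher change in females, and 0 of them passed with an estimated correlation (adjusted p = 0.496 to 0.643 with an estimated correlation, Benjamini-Hochberg). The smallest camera adjusted p were those of late activity (median 0.31, adjusted p = 0.000142), basement membrane (0.29, 0.000505), meningeal (0.56, 0.000505), heat shock (0.20, 0.00116), inflammatory (0.36, 0.00233), critical-period (0.14, 0.00276) and perineuronal net genes (0.13, 0.00276; Benjamini-Hochberg). The others called were red blood cells (0.45), proliferating cells (0.43), microglia (0.17), MMP-9 substrates (0.13), astrocytes (0.12), vessel cells (0.21), oligodendrocyte precursors (0.12), the glutamatergic synapse (0.08), regulators of translation (0.08) and ribosomal proteins (0.05), at camera adjusted p of 0.00744 to 0.0410 (Benjamini-Hochberg). Beside the 5 immediate-early genes and Hsph1, list members that passed over all genes with a higher change in females were Aqp4 (astrocytes), Hapln4 (perineuronal net), Hspg2 (basement membrane), Nrn1 (late activity), Shank1 and Shank3 (synapse), Rgs5 (vessel cells), Col1a2 (meninges), Hbb-bs and Hbb-bt (blood), Atf4 (heat shock), Mmp15 (metalloproteases), Atp5e (respiratory chain), and mt-Nd4 and mt-Nd5 (mitochondrial mRNAs). Beside Junb and Miat, those with a lower change were Rprm (deep layers), Ppp1r1b (striatum and thalamus) and Meg3 (noncoding RNA). These members were chosen after their values were seen. Xist, also chosen so, was among the 144 at 3.48 (SE 0.19). It had 6911, 6164 and 7056 counts in the WT, het and UTRmut females and 268, 15 and 5 in the males. Its difference thus came from the males, through the count of the WT male library, and not from a rise in females. Mmp9 had a difference of -0.05 (SE 0.60), and Timp1 to Timp4 had 0.58 (SE 0.64), -0.05 (SE 0.07), 0.39 (SE 0.11) and -0.30 (SE 0.12), none of which passed. Each cell of sex and genotype held 1 library, the WT female library stood lowest for many lists, and the count was 24 without WT replicate 1, 94 without UTRmut replicate 1, 406 without UTRmut replicate 2 and 736 without het replicate 2. DESeq2 called 76 genes and the unadjusted p was under 0.05 in 2190. With the TEC share as a covariate 265 genes passed, of which 61 were among the 194, and Atp11b, Leng8, Luc7l3, Miat and Rps6ka5 were lost (edgeR, Benjamini-Hochberg adjusted p = 0.0605 to 0.439).

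**Figure D4:**
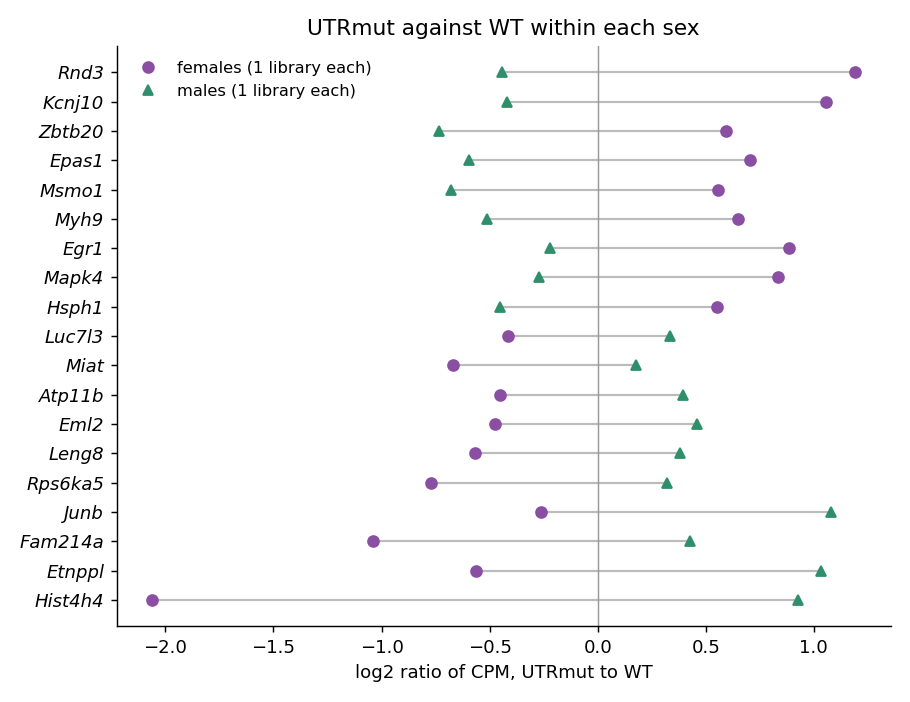
Log2 ratio of CPM, UTRmut to WT, in females (circles) and males (triangles) for 19 named genes whose change per allele differed between the sexes, 1 library per point's numerator and denominator. Each gene lies on opposite sides of 0 in the 2 sexes, as the naming rule required, from -2.06 against 0.93 in Hist4h4 to 1.19 against -0.44 in Rnd3.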

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

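The test against the share of TEC-class transcripts and the counts over other assignments were planned before their values were seen, and the alternative with that share as a covariate was chosen after.

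A difference between the sexes in the change per mutant allele, by a test of the interaction itself, set apart 194 genes. The 20 named genes are those with the smallest p that met the naming rule. Female minus male, on the log2 scale per allele, Baiap2l1 had 4.64 (0.310 without UTRmut replicate 1), Rnd3 0.816, Kcnj10 0.739, Zbtb20 0.662, Epas1 0.648, Msmo1 0.617, Myh9 0.576, Egr1 0.554, Mapk4 0.551 and Hsph1 0.501. Hist4h4 had -1.44, Etnppl -0.808, Fam214a -0.729, Junb -0.673, Rps6ka5 -0.549, Leng8 -0.472, Eml2 -0.467, Atp11b -0.423, Miat -0.423 and Luc7l3 -0.375.

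Of 100 assignments of the 6 libraries to the cells of the design, 2 gave at least as many genes, the real one included (194, and 221 in the other, which sets the same 4 WT and UTRmut libraries in the same contrast with its sign turned). As many genes were thus rare under random assignment, with a median of 2 over the other assignments, though some of these gave 155 and 104. A random assignment is not excluded by this, nor is a difference between single libraries, since each cell holds 1. A difference between libraries in the share of unspliced and nuclear RNA could also part the cells, since TEC transcripts were highest in the WT and het females: 67.5% of the 194 genes (131) had opposite signs in the female against male effect and in the interaction, against 58.0% of all genes tested, which lies between the values named in advance for and against. With 1 library per cell, an effect of the allele that depends on sex, which was not tested apart from the libraries, cannot be told apart from a property of single libraries.

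Without WT replicate 1 the count was 24, of which 13 were among the 194. The 20 named differences all kept their sign without it, and many their size (Kcnj10 0.709, Epas1 0.629, Egr1 0.559 and Fam214a -0.817, against Etnppl -0.565 and Rps6ka5 -0.357). In that fit the change in females rested on the het and UTRmut females alone, 1 library each. The change in males stayed in it, and the naming rule had set that opposite to the change in females. Whether the WT female library made the pattern thus stays open. With the TEC share as a covariate 265 genes passed, of which 61 were among the 194 and 133 of the 194 did not pass. Of the 20 named genes 15 passed under it. The covariate left fewer than the 2 residual degrees of freedom of the interaction fit, so a lost call under it does not show a smaller difference.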

How the results depend on the processing

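The alternative with the share of TEC-class transcripts as a covariate was chosen after seeing the data, and the others were planned.

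Over the named genes, 2659 values of alternatives kept direction and side of the threshold, 63 lost and 74 gained the threshold, and 67 changed sign. The cause was not tested, save where fewer genes or libraries entered by construction. Mmp9 gave no value under the stricter filter, which removes it.

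Without a filter on low counts, 27 genes passed in UTRmut against WT, 13 in het against WT, 28 in UTRmut against het, 19 per allele, 92 between the sexes and 600 for the interaction. The DESeq2 Wald test called 5 in UTRmut against WT, 6 in UTRmut against het, 3 per allele and 76 for the interaction. With the replicate block (sex), 4 passed in UTRmut against WT, 3 in het against WT, 5 in UTRmut against het and 0 per allele (edgeR). With only the 2 genotypes compared, 3, 1 and 10 passed, and Rn7s1 was lost in both comparisons that had called it. Without mitochondrial, ribosomal and small structural RNAs, which removes Rn7s1, 1 passed in het against WT and 1 in UTRmut against het. Without robust estimation 1 passed in UTRmut against het, where the Gm37176 call was lost, and 121 for the interaction. With no genotype term 8 passed between the sexes, and the Pttg1 call was lost. The stricter filter left 0 genes between the sexes (edgeR), since it removes the 4 Y-linked genes and Pttg1 and ends the call of C230004F18Rik, and an adjusted p under 0.1 gave 421 for the interaction. With the TEC covariate 2, 5 and 4 genes passed in the 3 comparisons of genotypes, and 265 for the interaction, of which 61 were among the 194.

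For lists, the estimated correlation and fry each called 0 in the 3 comparisons of genotypes. Without a filter 1 list was called in het against WT, and the TEC covariate gave 8 in UTRmut against WT.

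Timp2 changed sign in UTRmut against WT with DESeq2 size factors (0.00220), no filter (0.00439), DESeq2 (0.00677), without structural RNAs (0.00310) and with the TEC covariate (0.0415), in UTRmut against het with library size alone (-0.0508), and per allele (0.00111, 0.00221, 0.00341, 0.00156 and 0.0177 in the same order). With the TEC covariate Timp3 was -0.0323 in UTRmut against WT and -0.00395 per allele, and Mmp9 was -0.0900 in UTRmut against het and 0.0364 for the interaction.

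Leaving out each library in turn gave 0 to 103 genes in UTRmut against WT (0 without UTRmut replicate 2, 103 without WT replicate 2), 1 to 30 in het against WT (30 without WT replicate 2), 0 to 10 in UTRmut against het, 0 to 36 per allele, 5 to 197 between the sexes and 24 to 736 for the interaction, and 5 to 10, 2 to 13 and 4 to 11 lists in the 3 comparisons of genotypes.

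Log2 folds changed sign over these fits as follows. In UTRmut against WT, Timp1 ranged from -0.197 to 0.807, Timp2 from -0.0297 to 0.0240, Timp3 from -0.143 to 0.286 and Timp4 from -0.0490 to 0.357. In het against WT, Acan ranged from -0.0129 to 0.952, Rn7s2 from -0.592 to 0.463, Timp1 from -0.0792 to 0.933, Timp2 from -0.0952 to 0.0677, Timp3 from -0.0431 to 0.339, Timp4 from -0.104 to 0.0782, Malat1 from -0.0159 to 0.448 and Itgb1 from -0.0263 to 0.204. In UTRmut against het, Timp1 ranged from -0.440 to 0.266, Rn7sk from -0.203 to 0.00802, Timp2 from -0.0683 to 0.0946, Timp3 from -0.292 to 0.137, Ier2 from -0.0434 to 1.04, Mmp9 from -0.244 to 0.644 and Timp4 from -0.0348 to 0.371. Per allele, Timp1 ranged from -0.101 to 0.274, Timp2 from -0.0144 to 0.0119, Timp3 from -0.0416 to 0.144 and Timp4 from -0.0229 to 0.156. Between the sexes, Timp3 ranged from -0.350 to 0.0404, Timp1 from -0.305 to 0.507, Timp2 from -0.000266 to 0.112 and Timp4 from -0.162 to 0.150. For the interaction, Timp1 ranged from -0.118 to 1.43, Mmp9 from -0.749 to 0.821 and Timp2 from -0.144 to 0.0396.

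Replicate numbers follow sex, and the labels name nothing else that they share. Their deviations from the group mean correlated across genes at 0.295 for WT and het, 0.0802 for WT and UTRmut and 0.196 for het and UTRmut. Depth limits what can be seen of Mmp9 and Timp1, with 4 to 16 counts per library.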

Other observations

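The tests on Catspere1 and Catspere2 and on rRNA, and the repeat of the window test without Dbndd2, were chosen only after the results were seen. The window test around Mmp9 was itself prompted by the small p of Dbndd2 per allele, and was planned before its own values were seen.

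Catspere1 and Catspere2 were higher in both genotypes that carry the mutant allele. Reads moved from one paralog to the other would leave their sum unchanged, and the sum was higher in the 4 carriers by 1.84 on the log2 scale, which argues against this. A background haplotype on chromosome 1, segregating independently of the mutation on chromosome 2, could give the same picture: 9 other autosomal genes had at most 3 counts in some libraries and at least 20 in all the rest along divisions other than genotype, and 2 of 6 libraries drawn at random are both WT with a probability of 0.0667. That probability holds for a gene fixed in advance, while Catspere1 was singled out after it was seen to follow genotype. The chance that some gene does so is thus higher. An effect of the mutation was not tested apart from such a haplotype.

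Both classes of rRNA took a larger share in UTRmut. The nuclear rRNA share was higher by 0.647 on the log2 scale. Different removal of rRNA during library preparation would raise it too, but this rise is part of the observation, so the explanation stays open. Within UTRmut the classes ranked in opposite order, at 6.31% and 8.69% for mitochondrial and 0.261% and 0.191% for nuclear rRNA in the female and the male. More mitochondrial RNA as a whole is argued against: the median of 10 mitochondrial mRNAs was 0.0353 (SD 0.183), against 0.878 for mt-Rnr1 and 0.596 for mt-Rnr2. A change of rRNA with genotype was not tested apart from library preparation.

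Dbndd2 lies 0.455 Mb from Mmp9. The 86 genes tested within 5 Mb of Mmp9 had a mean -log10 p per allele at the 95.9 percentile of 10000 windows, and at 88.9 without Dbndd2, the gene that prompted the test, so whether genes near Mmp9 change as a group stays open.

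For females against males, 3 of the 10 splits of the 6 libraries gave at least 6 genes, the real one included, and the highest other gave 125. With 10 splits no share under 0.05 can be reached. With genotype in the model, the splits with 125 genes both compare the WT female with the WT male, 1 library each, and are the same contrast. Among the splits that divide the 2 libraries of every genotype, those other than the real one gave 3, 0 and 0 genes. Such splits are also too few for a share under 0.05.

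Ttr, abundant in choroid plexus, had 2, 7 and 6 counts in the WT, het and UTRmut females and 487, 3 and 74 in the males. Xist had 268 counts in the WT male. Genes at 3 or fewer counts in some libraries and at least 20 in the others included Bfsp2 (35, 3, 34 in the females and 3, 38, 60 in the males, in the order WT, het, UTRmut) and Eno1b (1, 1, 2 and 3, 273, 0), chosen after their values were seen.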
